A study of Caenorhabditis elegans with 119 samples.

How the data were processed

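RNA from whole adult Caenorhabditis elegans was sequenced in 119 libraries. Per the labels' protocols, worms were kept at 20 °C and moved on day 1 of adulthood to plates with 51 µM of FUdR, a drug that blocks the growth of progeny. The plates held sulforaphane (SFN), an isothiocyanate from broccoli, or its solvent DMSO, at a final DMSO concentration of 0.25%. About 50 worms were collected per library, and RNA was turned into libraries with a KAPA mRNA HyperPrep kit. Replicates were biological, per the labels' protocols, and were aged and collected together, except that replicates 4 to 6 of the strain EU1 were collected at separate times.

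The deposited values were raw read counts per gene for 46926 genes in each of 3 tables. The first table held the SFN and DMSO libraries of the wild-type strain N2, the second held 40 further N2 DMSO libraries from trials 2 and 3, and the third held the mutant strains. The authors made these counts with featureCounts of Subread 2.0.2 on the genome build WBcel235, per the submitters' processing notes. For the first table, reads were counted over exons and summed per gene on Ensembl release 108, with no strand setting, per the file headers. The aligner, the trimming of reads and the treatment of multiply mapped reads in the other tables were not given in the sources used here. Because counting used no strand in the first table, reads of a gene and of an overlapping antisense gene could not be told apart. Members of multigene families such as glutathione S-transferases, collagens, histones and major sperm proteins may share reads between near-identical copies, so single members are uncertain. Gene symbols and coordinates came from Ensembl release 115 of WBcel235, in which all 46926 identifiers were found.

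Each count column was matched to its library by name, and none was left unused. All 199 pairs of replicates within groups were compared before averaging, and none was identical. Their chi-square per degree of freedom ran from 2.29 to 286, so every library was counted as a separate replicate. Total counts ran from 0.445 to 12.5 M per library in the first table, from 1.07 to 8.61 M in trials 2 and 3, from 0.585 to 5.46 M in PX991 and from 2.06 to 10.3 M in EU1. Genes detected were compared after rarefying each library to the smallest total.

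Main tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM, and quasi-likelihood F tests were run with robust dispersion estimates. The p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and an adjusted p under 0.05 counted as past the threshold. The 40 libraries of the first table were fitted together with 1 term per group, which left 30 residual degrees of freedom. PX991 and EU1 were each fitted alone, and EU1 had a further term for its collections. The response of a mutant was compared with that of N2 by the difference of the SFN effects, in 1 model over N2, PX991 and EU1 at days 4 and 12. Because N2 and the mutants were in separate tables, strain levels set side by side also differ by table. Ages in trials 2 and 3 were compared with trial as a term. Values are given as CPM, counts scaled to a library of 1e6, with TMM scaling, mean ± SD, and fold changes on the log2 scale with their SE. A fold against a group with 0 counts is given as a lower bound against a floor of 3 counts over the group. Where the reference group held 1 to 3 counts, the levels are given in CPM.

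A set of 30 gene lists was written from textbook knowledge. They covered SKN-1 and phase II detoxification, glutathione S-transferases, UDP-glucuronosyltransferases, cytochrome P450s, the sulfide, cysteine and HIF-1 response, DAF-16 class I and class II targets, antioxidant enzymes, cytosolic heat shock proteins, and the mitochondrial and endoplasmic reticulum unfolded protein responses. Innate immune effectors, the heavy metal response, cuticle collagens, ribosomal proteins, the nuclear-encoded respiratory chain, protein genes of the mitochondrial genome, proteasome subunits, autophagy and lysosome, lipid metabolism and vitellogenins followed. The remaining lists were oocyte and germline, sperm, late embryo and larva, body wall and pharyngeal muscle, neurons, intestine, hypodermis, neuropeptides and core histones, which hold markers of the cell types in a whole worm. Some genes stand in more than 1 list. The symbols sqrd-2, sodh-1, pes-2, hsp-16.11, hsp-16.49, numr-2, cdr-5 and opt-2 did not match the annotation and were left out. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over all 298 tests of lists, and again with an estimated correlation. Members past the threshold were counted over all genes and adjusted over the list alone.

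Sets of 300 age-rising and 300 age-falling genes were defined from trials 2 and 3 alone, by the slope on age. They were taken from 3494 rising and 3454 falling candidates, so the SFN libraries had no part in their choice. An elastic net (glmnet 4.1.10, alpha 0.5, 8 folds) was trained on the 40 libraries of trials 2 and 3 to predict age in days from log2 CPM with a prior count of 2. It gave weight to 65 of 11778 genes. Predicted ages were compared by exact two-sided permutation tests over all splits, or with 100000 permutations where groups were pooled over ages.

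The groups, the tests, the gene lists, the rule for named genes and the main list of alternatives were fixed before the data were examined. The rule named, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and the same direction in every SFN library. To these it added up to 4 members per list with the lowest p, and daf-16, skn-1, gst-4, gcs-1 and sod-3 whatever their result. Genes named outside it are said to have been chosen after their values were seen.

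Each step was tested on simulated data before it was run on the real counts, the gene tests with 200 changed genes. In the simulation of N2 at day 8, with 12561 genes tested, 61 of 100 genes changed 2-fold and 89 of 100 changed 4-fold were recovered, and 9 of 12324 unchanged genes were called. In the simulated difference between EU1 and N2 at day 12, with 12299 genes, 39 of 100 and 76 of 100 were recovered. For a simulated difference of -4 days at N2 day 12, over 11778 genes, the age predictor returned -4.07 days.

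The replicate numbers of EU1 were taken as pairs. For replicates 4 to 6 the labels give separate collections, and same-numbered SFN and DMSO libraries deviated together from their group means, with correlations across genes of 0.1 to 0.26 at day 4 and 0.12 to 0.46 at day 12, though only 3 of 5 and 3 of 6 correlated best with their own number. Alternatives covered DESeq2 1.42.0 as test and its size factors as scaling, limma-voom with quality weights, other filters, replicate blocks, fits of the 2 compared groups alone, other age predictors and sets, and each library left out in turn. Fits without libraries that stood apart, fits without rRNA genes and age predictors without SFN-responsive genes were chosen after seeing the data.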

Results

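RNA was sequenced in adults of 3 C. elegans strains kept on SFN or its solvent DMSO. The wild-type strain N2 was sampled at days 2, 4, 8, 12 and 16 with 4 libraries per treatment and age, 40 in all. A further 40 N2 libraries from trials 2 and 3 held DMSO worms of the same ages, 4 per age and trial. PX991, a daf-16(fx107) strain, was sampled at days 4 and 12 with 4 libraries per group, and EU1, a skn-1(zu67) strain, at the same ages with 6 libraries per group, except 5 for SFN at day 4. DAF-16 is the FOXO transcription factor of the insulin signalling pathway, and SKN-1 is the Nrf-type factor that drives detoxification genes. Total counts per library had medians of 4.89 M (in units of 1e6 counts) in the N2 treatment table, 3.37 M in trials 2 and 3, 2.29 M in PX991 and 3.98 M in EU1.

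The mutated genes were looked at first in every group. Counts of skn-1 (WBGene00004804, chromosome IV, 5651039 to 5660384 in WBcel235) were low in EU1, at 107 ± 14 CPM (SD, n = 6) in DMSO and 95 ± 15 CPM (n = 5) in SFN at day 4. At day 12 they were 124 ± 24 CPM and 98.5 ± 15 CPM (n = 6 each). Every EU1 library lay between 77.2 and 149 CPM, while the groups of the N2 treatment table averaged 243 to 302 CPM and those of PX991 173 to 232 CPM. This difference in level was not tested, and N2 and the mutants were counted in separate tables. Counts of daf-16 (WBGene00000912, chromosome I, 10750498 to 10776703) in PX991 were 164 ± 13 CPM in DMSO and 154 ± 25 CPM in SFN at day 4, and 136 ± 14 CPM and 101 ± 30 CPM at day 12 (n = 4 each). Group means of daf-16 were 140 to 242 CPM in the N2 treatment table and 188 to 232 CPM in EU1. The labels do not say what the fx107 allele changes, so reads over daf-16 neither check nor contradict the genotype of PX991. In its own mutant neither gene passed the test of SFN against DMSO (edgeR, adjusted p = 1 and 0.22 for daf-16 in PX991 at days 4 and 12, and 0.55 and 0.052 for skn-1 in EU1). The day 12 fold change of skn-1 was -0.33 ± 0.12 on the log2 scale, lower in 6 of 6 libraries. It passed the threshold without DMSO replicate 1 (0.048), DMSO replicate 3 (0.027) or SFN replicate 6 (0.04).

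**Figure D1:**
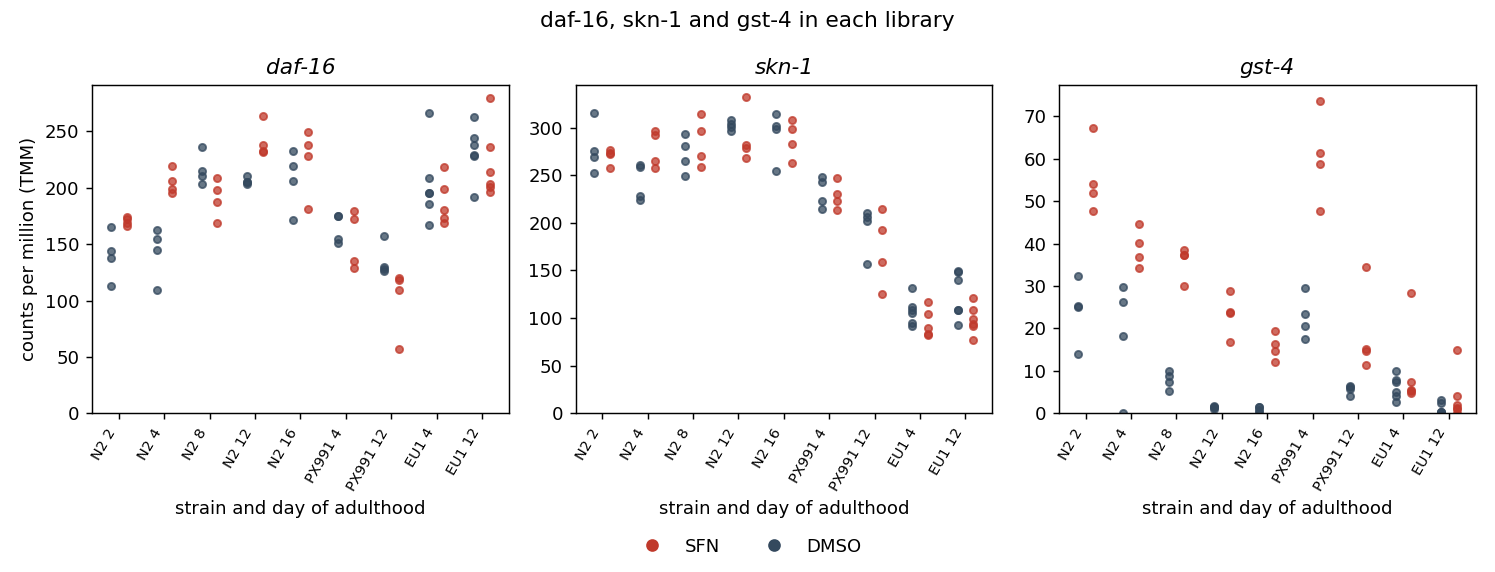
Levels of daf-16, skn-1 and gst-4 in each library in CPM, by strain, treatment and day of adulthood. The skn-1 values of EU1 lie between 77.2 and 149 CPM, below the group means of 243 to 302 CPM in the N2 treatment table.

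The first question was which genes SFN changes in young wild-type worms. At day 2, the steroid dehydrogenase family gene stdh-2 (WBGene00008678, chromosome V, 16224327 to 16225655) rose by 4.66 ± 0.44 on the log2 scale (SE, n = 4 per group). The glutathione S-transferase gst-31 rose by 4.58 ± 0.65 and the cytochrome P450 cyp-13A10 (WBGene00014254, chromosome II, 9660839 to 9662884) by 4.45 ± 0.48. The uncharacterised gene C15B12.8 (WBGene00015788, chromosome X, 6474264 to 6476645) rose by 4.99 ± 0.53, and gst-37 (WBGene00001785, chromosome V, 1921621 to 1922381) was at 12 ± 4.6 CPM against 0 counts in DMSO, a rise of at least 6.01. The cadmium-responsive gene cdr-4 (WBGene00010470, chromosome V, 12407366 to 12408625) rose by 3.06 ± 0.22, gst-5 (WBGene00001753, chromosome II, 10950352 to 10951603) by 3.04 ± 0.21, and gst-35 by 3.22 ± 0.75. The adjusted p of these genes ran from 5.6e-13 to 0.011 (edgeR quasi-likelihood test), with the rise in 4 of 4 SFN libraries for each. The SKN-1 target gst-4 (WBGene00001752, chromosome IV, 10142225 to 10143099) is a common reporter of oxidative stress. Its level was 55.3 ± 8.4 CPM against 24.2 ± 7.6 CPM, a rise of 1.26 ± 0.29 (adjusted p = 0.0096, 4 of 4 libraries), which missed the threshold without SFN replicate 3 (0.052). Of 77 ribosomal protein genes, in a list that did not hold with an estimated correlation (camera adjusted p = 0.13), 43 passed the test downward and 0 upward, 67 when adjusted over the list alone. Among them were rps-19 at -0.60 ± 0.12, rps-6 at -0.52 ± 0.11 and rpl-11.1 at -0.50 ± 0.11.

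Across the genome, 551 of 12735 genes passed the test at day 2, 344 higher and 207 lower with SFN (edgeR, adjusted p under 0.05). With camera at the preset correlation, 8 of 30 lists passed. Upward were the glutathione S-transferases (9 of 37 members rose, 10 adjusted over the list alone, adjusted p = 2.3e-05), SKN-1 and phase II detoxification (8 of 24 rose and 1 fell, 0.00053) and the UDP-glucuronosyltransferases (4 of 58, 0.00099). Downward were the ribosomal proteins (1.8e-45), the proteasome subunits (5 of 33 fell, 1.3e-13), the nuclear-encoded respiratory chain (3 of 40 fell, 2e-09), the oocyte and germline list (0.00025) and the antioxidant enzymes (2 of 22 fell, 0.0028). None of the 8 held with an estimated correlation, with camera adjusted p = 0.12 to 0.6. DMSO libraries of day 2 showed 9294 ± 1467 genes at a common depth against 10716 ± 81 with SFN, and rRNA took 1.31 ± 0.55% of their counts against 6.65 ± 2%. The count fell to 352 without SFN replicate 2, 183 without replicate 3 and 278 without replicate 4. The 207 falls became 340 and 396 without DMSO replicates 1 and 4. The count was 1124 without the 2 DMSO libraries that showed the fewest genes, day 2 replicate 1 and day 4 replicate 4, a fit chosen after seeing the data. The count and its direction depended on the fit: 28 genes passed with only the 2 groups (19 higher, 9 lower), 1589 with limma-voom weights (604 and 985), 642 with the strict filter (305 and 337) and 500 higher and 624 lower without those 2 DMSO libraries. The column names of the N2 treatment table give wells, 2 of which (A2 and A5) occur 2 times each, so at least 2 plates were used. The plates are not named, so these labels do not separate plate from treatment at any age.

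At day 4, C15B12.8 rose by 5.41 ± 0.43, cyp-13A10 by 4.67 ± 0.45, F21C10.9 by 4.41 ± 0.71, gst-5 by 3.51 ± 0.22 and cdr-4 by 2.81 ± 0.23 (n = 4, edgeR adjusted p from 2.1e-14 to 5.2e-05, higher in 4 of 4 SFN libraries each). With 1 to 3 counts in DMSO, stdh-2 was at 31.6 ± 3.6 CPM in SFN against 0.0448 ± 0.09 CPM, gst-31 at 13 ± 0.8 CPM against 0.134 CPM, and gst-37 at 10.1 ± 1.3 CPM against 0.0448 CPM. Genes of the mitochondrial genome moved in both directions. ND6 (WBGene00010957, MtDNA 113 to 549) fell by 2.67 ± 0.37 on the log2 scale. Falls also passed for ND3 (MtDNA 11356 to 11691) at -3.03 ± 0.55, WBGene00010958 (MtDNA 549 to 783) at -2.70 ± 0.46 and WBGene00010961 (MtDNA 3389 to 4269) at -3.74 ± 0.57 (adjusted p from 1.8e-05 to 0.00051). COX3 rose by 0.72 ± 0.19 (0.013). The difference of gst-4 was 0.85 ± 0.29 (adjusted p = 0.053, 4 of 4 libraries), which passed without DMSO replicate 2 (0.035) or DMSO replicate 3 (0.031).

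In all, 1311 of 12735 genes passed at day 4, 899 higher and 412 lower with SFN, but 2209 with the DESeq2 test, 855 and 694 with the strict filter and 1060 and 238 with no filter. The glutathione S-transferases (12 of 37 rose, 15 adjusted over the list alone, camera adjusted p = 6.1e-06), UDP-glucuronosyltransferases (8 of 58, 1.4e-05), cytochrome P450s (12 of 50 rose and 1 fell, 0.00013) and SKN-1 and phase II list (5 of 24, 0.00047) passed upward. So did genes of body wall and pharyngeal muscle (12 of 20 rose, 17 adjusted over the list alone, 3.6e-08), cuticle collagens (17 of 59, 0.00043) and neuropeptides (7 of 87, 0.00057). Lipid metabolism (13 of 39, 0.0072), intestine (5 of 23 rose and 1 fell, 0.033) and neurons (3 of 20, 0.045) passed upward too. Proteasome subunits (7 of 33 fell, 1.2e-11), ribosomal proteins (4 of 77 fell and 1 rose, 3.9e-06), the 12 mitochondrial genome genes (4 rose and 4 fell, 0.0055) and sperm genes (0 of 32 passed, 0.026, with a median of 0) passed downward. For the sperm genes test, mean and median differ in sign. No list held with an estimated correlation, with camera adjusted p = 0.15 to 0.77 for these 14. Genes seen at the common depth numbered 9434 ± 1928 in DMSO and 11250 ± 59 in SFN, and the rRNA share was 1.38 ± 0.55% against 2.85 ± 0.88%. The count was 755 without SFN replicate 1, 760 without SFN replicate 2, 821 without DMSO replicate 2 and 2167 without DMSO replicate 3, the falls were 623 without DMSO replicate 4, and the count was 2313 without the 2 DMSO libraries that showed the fewest genes, a fit chosen after seeing the data. With only the 2 groups 41 genes passed (37 higher, 4 lower), and with limma-voom weights 791 (383 and 408).

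At day 8, the invertebrate lysozyme ilys-3 (WBGene00016670, chromosome IV, 2464456 to 2465443) was at 2.23 ± 0.64 CPM with SFN against 116 ± 32 CPM in DMSO, a fold change of -5.75 ± 0.35 on the log2 scale (edgeR adjusted p = 2.7e-15). Its relative ilys-2 fell by 4.39 ± 0.44 (6.6e-10). The lipase gene lips-13 fell by 5.27 ± 0.59 on the log2 scale, with the saposin-like spp-9 at -3.66 ± 0.37 and F14H12.3 at -3.50 ± 0.35 (adjusted p from 6.5e-10 to 2.6e-08). Upward, stdh-2 rose by 7.94 ± 0.49, C15B12.8 by 6.48 ± 0.39, gst-31 by 5.79 ± 0.67, cyp-13A10 by 4.60 ± 0.37 and the DAF-16-regulated dod-17 by 4.42 ± 0.59 (adjusted p from 3.4e-17 to 4.8e-07). The level of gst-5 was 282 ± 40 CPM against 13.6 ± 2.4 CPM, a rise of 4.33 ± 0.22 (4.9e-18), and gst-4 rose by 2.24 ± 0.31 (1.1e-06). Each of these genes moved the same way in 4 of 4 SFN libraries. Rises passed the test for 362 genes and falls for 87, or 449 of 12735 genes in all.

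Of the 30 lists, 17 passed at day 8, and 3 of them also with an estimated correlation. These were the glutathione S-transferases (15 of 37 rose, 23 adjusted over the list alone, camera adjusted p = 8.2e-26, and 0.023 with an estimated correlation) and SKN-1 and phase II detoxification (10 of 24 rose, 12 over the list alone, 5.1e-15 and 0.032). The third of them, which went downward, was sperm genes (7 of 32 fell, 24 adjusted over the list alone, with a median of -2.66, 2.4e-47 and 0.032). At the preset correlation, muscle (9 of 20 rose, adjusted p = 3.1e-12), vitellogenins (3 of 6, 1.9e-10), collagens (13 of 59, 6.8e-09), intestine (6 of 23, 2.1e-08) and cytochrome P450s (8 of 50, 2.3e-08) passed upward. So did UDP-glucuronosyltransferases (8 of 58, 4.4e-08), lipid metabolism (12 of 39 rose and 1 fell, 2.4e-07), innate immune effectors (12 of 39 rose and 2 fell, 1.4e-05), the heavy metal response (3 of 10, 0.0029) and the sulfide, cysteine and HIF-1 list (1 of 17, 0.03). The mitochondrial genome genes (0.0043) and ribosomal proteins (0.012) also passed upward, and proteasome subunits (0.0033) and the oocyte and germline list (0.013) downward, with 0 members past the threshold in each. These 14 lists did not hold with an estimated correlation, with camera adjusted p = 0.075 to 0.82. Libraries of the compared groups showed 11671 ± 117 genes (SFN) and 11867 ± 114 genes (DMSO) at the common depth, and the count of 449 fell to 270 without SFN replicate 1 and 278 without DMSO replicate 3. The 87 falls became 47, 142 and 53 without SFN replicates 1, 2 and 3, and 52 and 57 without DMSO replicates 3 and 4. It was 1287 with only the 2 groups, 1669 with limma-voom weights and 697 with no filter.

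At day 12, the fatty acid and retinol binding gene far-3 was at 695 ± 150 CPM with SFN against 8.69 ± 5.4 CPM, a rise of 6.29 ± 0.42 (n = 4, edgeR adjusted p = 5.4e-13). The level of stdh-2 was 111 ± 9.9 CPM against 0.267 CPM, a rise of 8.51 ± 0.40 (3.2e-21). Large rises were also those of gst-37 by 7.86 ± 0.53, gst-31 by 6.66 ± 0.54, cyp-13A10 by 5.96 ± 0.32, spp-12 by 5.94 ± 0.45, gst-35 by 5.38 ± 0.57 and ugt-25 by 5.25 ± 0.32 (adjusted p from 5.9e-19 to 2.4e-10). The level of gst-4 was 23.3 ± 4.9 CPM against 1.44 ± 0.26 CPM, a rise of 4.00 ± 0.33 (2.8e-13). Yolk protein genes rose: vit-3 (WBGene00006927, chromosome X, 3567355 to 3572549) by 4.18 ± 0.27, its close copy vit-4 by 4.19 ± 0.33 and vit-5 by 1.20 ± 0.18. Vitellogenins took 2.61 ± 0.57% of the counts against 1.3 ± 0.2%. The cathepsin B-like cpr-2 fell by 3.81 ± 0.30 on the log2 scale to 29.3 ± 4.9 CPM from 406 ± 180 CPM, and the thioredoxin gene trx-3 fell by 4.04 ± 0.42. The lysozymes ilys-2, lys-3 and ilys-3 fell by 3.58 ± 0.39, 3.26 ± 0.54 and 3.16 ± 0.26 (adjusted p from 4.6e-12 to 1e-05). Every gene of this paragraph moved the same way in 4 of 4 SFN libraries, and 2396 of 12735 genes passed in all, 1761 higher and 635 lower. The balance was closer with only the 2 groups (2438 higher and 1733 lower) and with limma-voom weights (2946 and 1957), and falls were 419 without DMSO replicate 1.

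The lists moved with them, 19 of 30 at day 12. Those that also held with an estimated correlation (camera adjusted p = 0.032 each) were the glutathione S-transferases (25 of 37 rose, 32 adjusted over the list alone), innate immune effectors (25 of 39 rose and 3 fell), vitellogenins (6 of 6 rose) and muscle (16 of 20 rose, 17 over the list alone). At the preset correlation their adjusted p were 4.3e-19, 1.6e-16, 1.9e-14 and 1e-20. Among their members, the antimicrobial C17H12.8 rose by 4.11 ± 0.28, the antimicrobial peptide gene nlp-29 by 2.73 ± 0.25, the troponin I gene unc-27 by 3.18 ± 0.24 and the thin filament gene unc-87 by 1.92 ± 0.17. Upward at the preset correlation were also collagens (27 of 59 rose, 5.5e-17), UDP-glucuronosyltransferases (32 of 58, 5.8e-11), SKN-1 and phase II detoxification (14 of 24, 1.5e-10), and lipid metabolism (22 of 39 rose and 2 fell, 7.3e-10). Mitochondrial genome genes (9 of 12, 1.1e-08), intestine (13 of 23, 2.4e-08), cytochrome P450s (27 of 50 rose and 1 fell, 4.1e-08), DAF-16 class I targets (11 of 18, 4.1e-05) and the sulfide, cysteine and HIF-1 response (6 of 17, 0.013) followed. Examples were col-181 at 3.62 ± 0.28, the fatty acid elongase elo-5 at 3.19 ± 0.31, the gut esterase ges-1 at 2.57 ± 0.25 and lys-7 at 2.57 ± 0.32. Proteasome subunits (6 of 33 fell, 1.4e-05), sperm genes (1 of 32 rose, 1.7e-05), the respiratory chain (4 of 40 fell, 0.0036), ribosomal proteins (3 of 77 fell, 0.01), core histones (4 of 25 fell and 1 rose, 0.011) and the oocyte and germline list (3 of 36 fell, 0.017) passed downward. With an estimated correlation these 15 lists gave camera adjusted p = 0.075 to 0.81.

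At the same age, the remaining 11 lists did not pass. They were the heavy metal response (camera adjusted p = 0.067, 4 of 10 members rose), mitochondrial unfolded protein response (0.16, 4 of 14 rose), DAF-16 class II targets (0.22, 3 of 8 rose and 1 fell), and late embryo and larva (0.22, 1 of 12 rose and 3 fell). Neuropeptides (0.26, 12 of 87 rose and 2 fell), endoplasmic reticulum unfolded protein response (0.32, 1 of 17 fell) and neurons (0.36, 2 of 20 rose and 1 fell) did not pass either. Antioxidant enzymes (0.58, 6 of 22 rose and 1 fell), hypodermis (0.63, 2 of 10 rose), autophagy and lysosome (0.67, 5 of 34 rose and 3 fell) and cytosolic heat shock proteins (0.84, 2 of 15 rose and 1 fell) made up the rest. For the heat shock proteins and the late embryo list, median, mean and test differ in sign. Single members of these lists still rose, such as the mitochondrial chaperonin hsp-60 at 0.96 ± 0.11 (edgeR adjusted p = 6.6e-10) and the glutathione peroxidase gpx-5 at 2.01 ± 0.30 (7.3e-07). The superoxide dismutase gene sod-3 (WBGene00004932, chromosome X, 17092753 to 17094306) rose by 2.40 ± 0.60 (0.0022). Each rose in 4 of 4 SFN libraries. The rRNA share was 2.93 ± 0.35% with SFN and 0.814 ± 0.26% in DMSO. A total of 3809 genes, 2066 higher and 1743 lower, passed without the 2 DMSO libraries of days 2 and 4 that showed the fewest genes, a fit chosen after seeing the data.

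**Figure D2:**
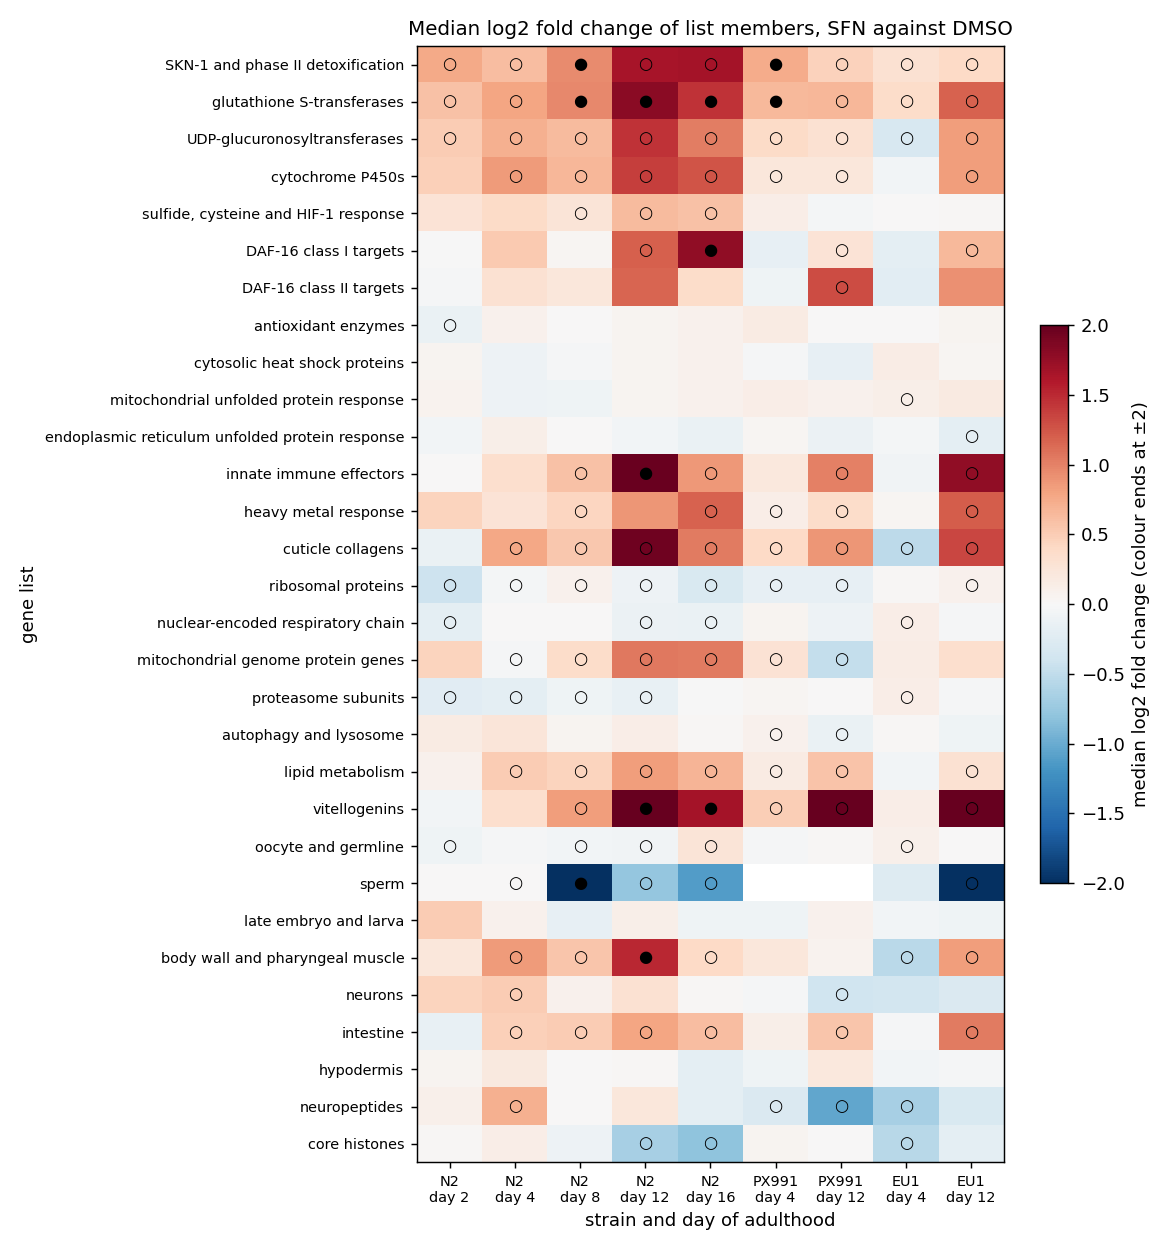
Median log2 fold change of each gene list, SFN against DMSO, in each strain and at each age, with colours ending at 2 in either direction. An open circle marks a list that passed camera at the preset correlation and a filled circle one that passed with an estimated correlation too, such as the glutathione S-transferases at days 8, 12 and 16 in N2.

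At day 16, the collagen-like clx-1 rose by 8.17 ± 0.74 and the collagen col-183 by 7.88 ± 0.55, while F56D6.9 rose by at least 6.93 from 0 counts in DMSO. As at day 12, gst-37 rose, here by 7.64 ± 0.51, cyp-13A10 by 6.97 ± 0.34, far-3 by 6.20 ± 0.46 and gst-5 by 4.35 ± 0.20, while stdh-2 was at 116 ± 20 CPM against 0.0792 CPM (n = 4, edgeR adjusted p from 4.1e-21 to 1.5e-08). Among the largest falls, pals-4 fell by 3.96 ± 0.53 and pals-14 by 3.36 ± 0.66 on the log2 scale (adjusted p = 1.3e-07 and 0.00019), with F14H12.3 at -3.20 ± 0.36 and skr-9 at -2.64 ± 0.31. The lysozyme ilys-3, which fell at days 8 and 12, rose at day 16 by 0.81 ± 0.23 (0.012). The rise of sod-3 was 2.14 ± 0.63 (0.013), which missed the threshold without DMSO replicate 2 or 4 (0.051 each). These changes ran in 4 of 4 SFN libraries per gene, and 2463 of 12735 genes passed, 1514 higher and 949 lower, but 1444 and 1204 with DESeq2 size factors, 2381 and 2064 with limma-voom, 1850 and 1594 with only the 2 groups, and 1908 and 1791 without the 2 DMSO libraries that showed the fewest genes. The falls were 571 and 623 without SFN replicates 1 and 2 and 617 without DMSO replicate 4.

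Of the lists, 19 passed at day 16, and 3 also with an estimated correlation: the glutathione S-transferases (24 of 37 rose, 25 adjusted over the list alone, camera adjusted p = 5.6e-18 and 0.032) and DAF-16 class I targets (16 of 18 rose, 3.5e-10 and 0.023), and vitellogenins (6 of 6 rose, 1.4e-12 and 0.039). DAF-16 class I members included lys-7 at 3.47 ± 0.33, the catalase ctl-2 at 1.90 ± 0.21 and the metallothionein mtl-1 at 2.15 ± 0.24. SKN-1 and phase II detoxification (17 of 24 rose and 1 fell, 1.1e-12), cytochrome P450s (27 of 50, 1.7e-11), collagens (23 of 59 rose and 1 fell, 2.3e-11), mitochondrial genome genes (9 of 12, 4.9e-10) and UDP-glucuronosyltransferases (25 of 58, 3.3e-08) passed upward at the preset correlation. In the same order they had adjusted p = 0.051, 0.19, 0.15, 0.13 and 0.37 with an estimated correlation. Oocyte and germline genes (17 of 36 rose and 1 fell) passed upward as well (camera adjusted p = 1.3e-05, and 0.46 with an estimated correlation). They were led by the chitin synthase chs-1 at 1.02 ± 0.13, the RNA-binding puf-5 at 0.61 ± 0.09 and the eggshell gene cpg-2 at 0.59 ± 0.09. Ribosomal proteins (21 of 77 fell, 6.5e-11) and core histones (7 of 25 fell, 0.0014) passed downward, but not with an estimated correlation (0.49 and 0.35). The core histone list also holds the linker histone his-24 (-1.55 ± 0.23). The other 8 did not hold with an estimated correlation either (0.21 to 0.6). Upward were innate immune effectors (15 of 39 rose and 1 fell, 1.6e-06), lipid metabolism (18 of 39 rose and 3 fell, 4.7e-05), muscle (7 of 20, 0.00035), intestine (10 of 23 rose and 3 fell, 0.00042), the heavy metal response (6 of 10, 0.0037) and the sulfide, cysteine and HIF-1 response (5 of 17 rose and 1 fell, 0.045). Downward were sperm genes (1 of 32 rose, 3.5e-07) and the respiratory chain (6 of 40 fell, 0.012). With SFN rRNA took 1.85 ± 0.17% of 3.23 to 5.89 M counts, and in DMSO 0.624 ± 0.09% of 8.11 to 10.4 M. The fit without the 2 DMSO libraries of days 2 and 4 gave 3699 genes and was chosen after seeing the data.

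**Figure D3:**
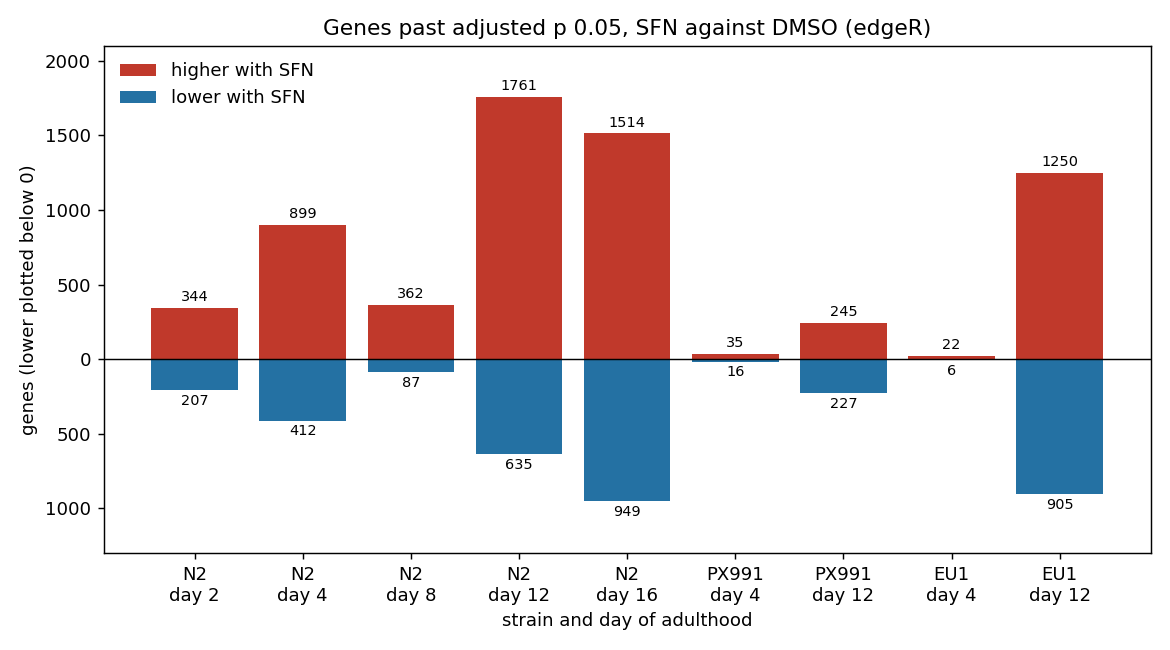
Number of genes past the threshold in each comparison, split into higher and lower. SFN gave 2396 and 2463 genes at days 12 and 16 in N2, 472 at day 12 in PX991 and 2155 at day 12 in EU1.

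Averaged over the 5 ages of N2, cyp-13A10 rose by 5.33 ± 0.17, gst-5 by 4.05 ± 0.10 and gst-12 by 3.42 ± 0.21, each in 20 of 20 SFN libraries (edgeR adjusted p from 1e-30 to 6.5e-18). Among the 82 genes past the threshold with a mean log2 CPM of at least 2 that fell in all 20 SFN libraries, the largest falls included srp-7 at -0.42 ± 0.05 and ahsa-1 at -0.38 ± 0.05 (1.8e-10 and 6.4e-09). The gene gcs-1 (WBGene00001527, chromosome II, 9035562 to 9038301), which encodes a subunit of the enzyme that limits glutathione synthesis and is a SKN-1 target, rose by 0.24 ± 0.05 on this mean (0.00052, 19 of 20 libraries) and passed at no single age. By this mean, 4325 of 12735 genes passed, 2850 higher and 1475 lower, but 2970 and 2725 without the 2 DMSO libraries that showed the fewest genes and 2095 and 1832 with the strict filter. The effect of SFN differed between ages for 1657 genes, including gst-4 (1.2e-07), ilys-3 (1.1e-12), vit-3 (1.7e-10), far-3 (5.8e-10), hsp-60 (1.5e-09), lys-7 (9e-08), unc-27 (1.8e-07) and ND6 (3.5e-05). It also differed for daf-16 (0.015, with a rise of 0.48 ± 0.11 at day 4 in 4 of 4 libraries, adjusted p = 0.0033), but not skn-1 (0.51) or gst-37 (0.91). Without the 2 DMSO libraries that showed the fewest genes, a fit chosen after seeing the data, it differed for 2915 genes.

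DMSO worms of different ages were compared to describe ageing without SFN. In trials 2 and 3, 7429 of 11778 genes differed between days 16 and 2, 3866 higher and 3563 lower at day 16, after 2009, 4651 and 6929 at days 4, 8 and 12. The yolk genes vit-3 and vit-4 fell, at -11.05 ± 0.34 and -10.89 ± 0.34 on the log2 scale, as did the collagen col-20 at -10.37 ± 0.51 and ilys-5 at -11.31 ± 0.73 (n = 8, lower in 8 of 8 libraries, edgeR adjusted p from 3.5e-24 to 2.5e-15). The protease cpr-2 rose by 9.75 ± 1.06, ilys-3 by 9.38 ± 0.61, C54F6.18 by 8.45 ± 0.51 and ilys-2 by 8.36 ± 0.63 (6e-17 to 1e-09). In the N2 treatment table, with other libraries, vit-3 stood at -11.79 ± 0.36, col-20 at -13.49 ± 0.50 and gst-4 at -4.45 ± 0.36 on the log2 scale, each lower in 4 of 4 libraries (edgeR adjusted p from 7e-23 to 2.2e-14). There, 6714 of 12735 genes passed at day 16, after 3368, 5545 and 6033 at days 4, 8 and 12. In trials 2 and 3 gst-4 fell by 3.27 ± 0.30 (1.2e-12). DESeq2's size factors moved the median of all genes by 0.12 between days 8 and 2 in the treatment table.

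The next question was whether SFN acts without DAF-16. In PX991 at day 4, C15B12.8 rose by 6.23 ± 0.42, cyp-13A10 by 4.30 ± 0.38, gst-5 by 3.55 ± 0.25, gst-35 by 3.26 ± 0.58 and cdr-4 by 3.01 ± 0.28 (n = 4, edgeR adjusted p from 3.5e-09 to 0.0046, higher in 4 of 4 libraries). The level of gst-5 was 170 ± 43 CPM against 14.3 ± 2.5 CPM. From 0 counts in DMSO, stdh-2 rose by at least 7.05 and gst-37 by at least 5.68. The reporter gene gst-4 rose by 1.40 ± 0.24 (0.0026) to 60.4 ± 11 CPM from 22.8 ± 5.1 CPM. Falls included the exchanger gene ncx-9 at -4.16 ± 0.68, ZK354.2 at -3.85 ± 0.60 and the transthyretin-like ttr-29 at -3.08 ± 0.40. In all, 51 of 10073 genes passed, 35 higher and 16 lower, but 96 with the DESeq2 test, 115 with no filter, 271 with limma-voom and 189 with only the 2 groups. SKN-1 and phase II detoxification (5 of 18 rose, 9 adjusted over the list alone, camera adjusted p = 3.8e-16 and, with an estimated correlation, 0.023) and the glutathione S-transferases (7 of 22 rose, 12 over the list alone, 3.9e-17 and 0.032) passed in both forms of the test. UDP-glucuronosyltransferases (4 of 42 rose, 1.5e-12), cytochrome P450s (2 of 39, 0.00017), the heavy metal response (2 of 9, 0.00039), mitochondrial genome genes (0.0018), collagens (0.0024), vitellogenins (0.0097), lipid metabolism (0.027) and autophagy (0.045) passed upward at the preset correlation alone. Ribosomal proteins (8.6e-13) and neuropeptides (1.3e-05) did so downward, and these 10 lists had adjusted p = 0.11 to 0.68 with an estimated correlation. The rRNA share was 19.7 ± 10% with SFN and 6.88 ± 5.7% in DMSO, and the count was 31 (22 and 9) without DMSO replicate 3 and 33 (23 and 10) without DMSO replicate 4. Falls were 9 without DMSO replicate 2 or SFN replicate 3, 6 without SFN replicate 2 and 28 with replicate blocks.

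In PX991 at day 12, the yolk gene vit-4 rose by 5.02 ± 0.56, vit-3 by 4.81 ± 0.38, stdh-2 by 5.16 ± 0.45, the saposin-like spp-9 by 4.92 ± 0.61, gst-37 by 4.33 ± 0.65 and lys-2 by 3.97 ± 0.86 (n = 4, edgeR adjusted p from 1.8e-06 to 0.016, higher in 4 of 4 libraries). Genes known as DAF-16 targets also rose in this strain, such as lys-7 at 3.09 ± 0.44, ctl-2 at 1.25 ± 0.25 and icl-1 at 1.46 ± 0.23 (adjusted p from 6e-04 to 0.0047, 4 of 4 libraries). F09C6.13 fell by 3.99 ± 0.57, C41G11.1 by 2.51 ± 0.26 and the neuropeptide gene nlp-8 by 2.32 ± 0.47 on the log2 scale. Of 10073 genes, 472 passed, 245 higher and 227 lower. These were 244 and 93 without SFN replicate 4, 233 and 118 without DMSO replicate 1, 169 and 262 without DMSO replicate 2, 214 and 335 with limma-voom, and 97 and 66 with only the 2 groups. Vitellogenins (6 of 6 rose, camera adjusted p = 8.6e-13), innate immune effectors (8 of 34 rose and 1 fell, 1.9e-07), lipid metabolism (7 of 36 rose and 1 fell, 9.2e-07), collagens (1.4e-06), and intestine (5 of 23, 2.6e-06) passed upward. UDP-glucuronosyltransferases (5 of 42, 0.00017), SKN-1 and phase II detoxification (3 of 18 rose and 1 fell, 0.00038) and glutathione S-transferases (5 of 22 rose and 2 fell, 0.00041) did as well. DAF-16 class II targets (3 of 8, 6e-04) and class I targets (5 of 14 rose and 1 fell, 0.012) passed upward, with cytochrome P450s (0.046) and the heavy metal response (0.041). Neuropeptides (11 of 63 fell and 1 rose, 31 fell adjusted over the list alone, 3.2e-08), ribosomal proteins (6.3e-05), mitochondrial genome genes (2 of 12 fell, 0.0016), neurons (4 of 18 fell, 0.013) and autophagy (0.021) passed downward. Of the neuron genes, the prohormone convertase egl-3 was at -1.35 ± 0.29. None of these 17 held with an estimated correlation, with camera adjusted p = 0.075 to 0.56. Genes at the common depth ran from 11186 to 15327 in SFN libraries, with rRNA at 14.1 ± 8.7% against 3.52 ± 1.9% in DMSO.

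Whether SFN acts with skn-1 mutated was asked in EU1. At day 4, C15B12.8 rose by 5.34 ± 0.48, cyp-13A10 by 3.61 ± 0.37, gst-5 by 3.13 ± 0.30, T16G1.7 by 3.07 ± 0.34 and cdr-4 by 2.66 ± 0.24 (n = 5 and 6, edgeR adjusted p from 5.6e-07 to 4.7e-05, higher in 5 of 5 SFN libraries). The level of gst-5 was 134 ± 14 CPM against 15.1 ± 7.4 CPM. That of stdh-2 was 20.7 ± 9.1 CPM against 0.0961 CPM, and that of gst-37 2.47 CPM against 0.0337 CPM (0.032). The call of gst-37 ended when 1 library was left out, at adjusted p = 0.077, 0.078, 0.064 and 0.07 without DMSO replicates 1, 2, 4 and 6, and 0.058, 0.058 and 0.051 without SFN replicates 2, 4 and 6. The level of gst-4 was 10.3 ± 10 CPM against 6.25 ± 2.7 CPM, a difference of 0.44 ± 0.71 (0.83, higher in 2 of 5 libraries). The fibroblast growth factor receptor egl-15 fell by 1.52 ± 0.26 on the log2 scale (0.0074). In all, 28 of 11170 genes passed, 22 higher and 6 lower, against 1569 at an unadjusted p under 0.05. Most were lower instead with the DESeq2 test (80 of 206 higher), with no filter (136 of 449) with only the 2 groups (8 of 19) and without DMSO replicate 3 (13 of 27).

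The same lists were tested in EU1 at day 4. SKN-1 and phase II detoxification (1 of 18 rose, 4 adjusted over the list alone, camera adjusted p = 0.00043), glutathione S-transferases (2 of 28, 6 over the list alone, 3e-04), proteasome (5.7e-06), respiratory chain (9.5e-05), oocyte and germline (0.0099) and the mitochondrial unfolded protein response (0.011) passed upward. Neuropeptides (8.5e-05), core histones (0.001), muscle (0.0054), collagens (0.021) and UDP-glucuronosyltransferases (0.041, and 0.056 with replicate blocks) passed downward, and none of the 11 held with an estimated correlation (0.15 to 0.69). The heavy metal response stood at 0.065, and at 0.047 with replicate blocks. Ribosomal RNA took 15.1 ± 18% of counts with SFN and 13.9 ± 11% in DMSO. The count of 28 genes was 285 in replicates 1 to 3 alone and 8 in replicates 4 to 6 alone. It was 15, 13, 107 and 15 without DMSO replicates 1, 2, 5 and 6, and 11, 10, 13, 91 and 13 without SFN replicates 2 to 6.

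In EU1 at day 12, stdh-2 rose by 8.06 ± 0.38, gst-37 by 6.15 ± 0.68, spp-9 by 5.28 ± 0.55, and the lysozymes ilys-5 by 5.11 ± 0.59 and lys-2 by 5.07 ± 0.50 (n = 6). In the same comparison vit-4 rose by 4.46 ± 0.45, gst-5 by 3.49 ± 0.30 and vit-3 by 3.39 ± 0.37 (edgeR adjusted p from 6.3e-13 to 4.5e-05 for these 8 genes, higher in 6 of 6 libraries). The level of gst-4 was 3.91 ± 5.6 CPM against 1.14 ± 1.3 CPM, a difference of 1.77 ± 0.79 (0.12, 5 of 6 libraries). F14F9.2 fell by 3.96 ± 0.76 on the log2 scale, with T05A8.2 at -3.15 ± 0.48, C27H5.6 at -2.99 ± 0.39 and lys-3 at -2.85 ± 0.56 (adjusted p from 2.5e-05 to 0.0031). Of 11170 genes, 2155 passed, 1250 higher and 905 lower. Innate immune effectors (21 of 35 rose, camera adjusted p = 5.9e-10), cytochrome P450s (22 of 47 rose and 1 fell, 7.8e-09), UDP-glucuronosyltransferases (21 of 49 rose and 1 fell, 4.1e-08), and vitellogenins (6 of 6, 4.1e-08) passed upward. Collagens (19 of 39, 8.7e-08), glutathione S-transferases (13 of 28 rose, 16 adjusted over the list alone, 5.5e-07), intestine (14 of 23 rose and 1 fell, 6e-07), and muscle (8 of 20, 2.8e-05) did too. The heavy metal response (5 of 9 rose and 1 fell, 0.0041), DAF-16 class I targets (6 of 18, 0.0075), lipid metabolism (0.0092), SKN-1 and phase II detoxification (5 of 18 rose and 1 fell, 0.022) and ribosomal proteins (0.023) completed the upward lists. Sperm genes (0.029) and the endoplasmic reticulum unfolded protein response (2 of 17 fell, 0.032) passed downward. None of the 15 held with an estimated correlation, with camera adjusted p = 0.15 to 0.81. The count was 1153 (738 and 415) with limma-voom, 653 in replicates 1 to 3 alone and 589 in replicates 4 to 6 alone. It was 1205 (772 higher and 433 lower) without DMSO replicate 4 and 1290 (813 and 477) without DMSO replicate 5, with 541 lower without SFN replicate 1.

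**Figure D4:**
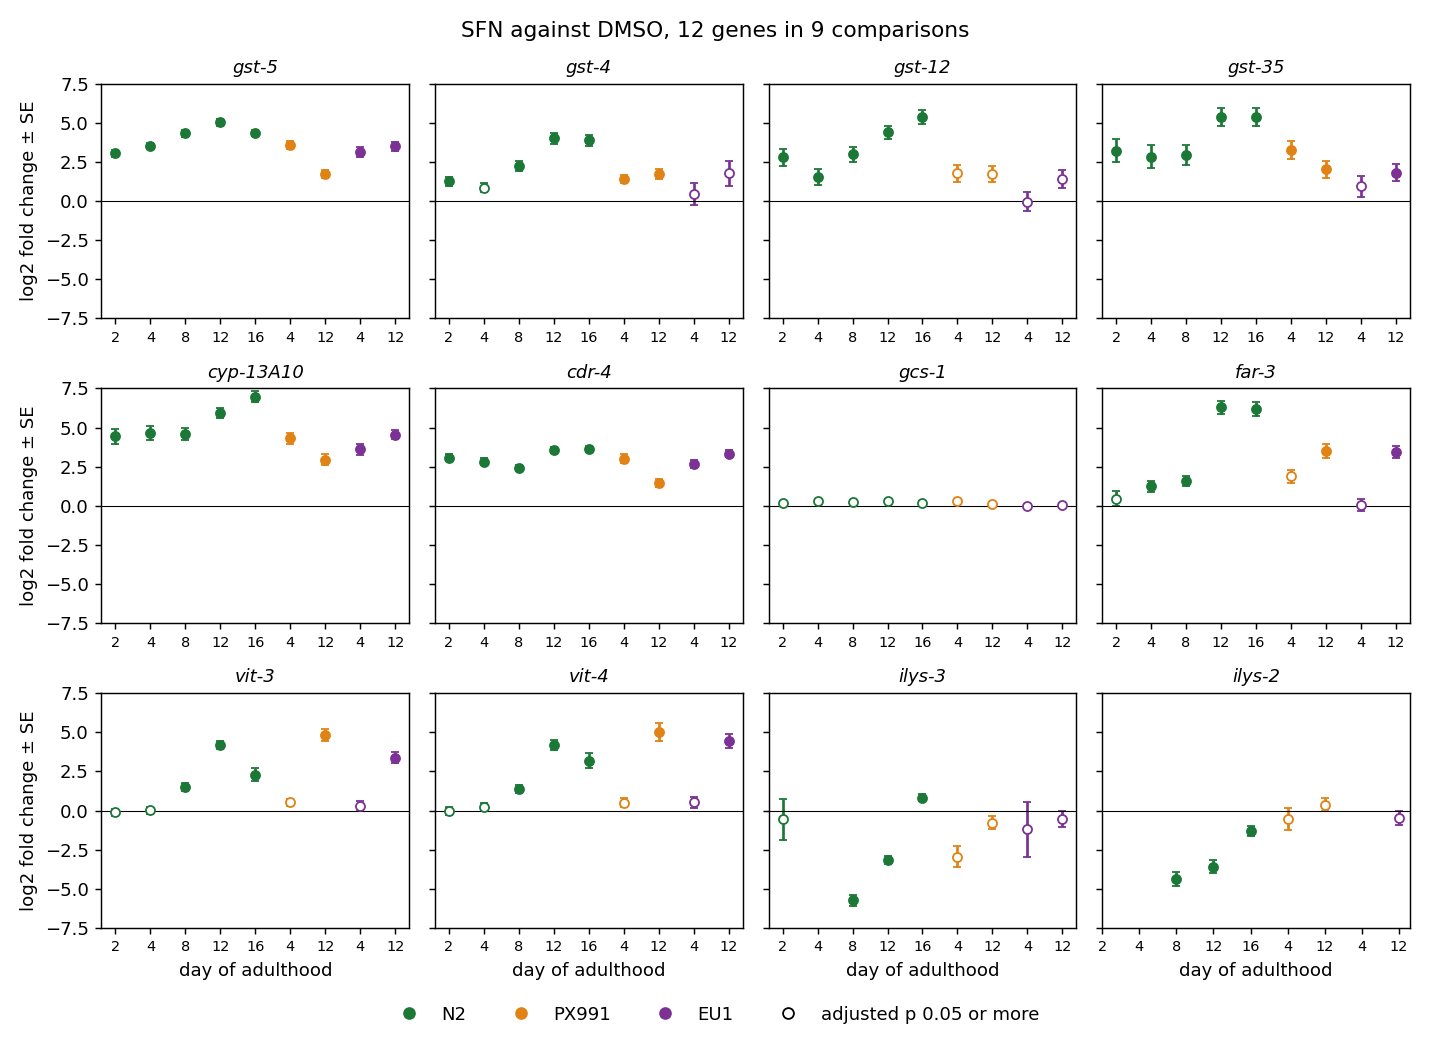
Log2 fold change, SFN against DMSO, of 12 genes in the 9 comparisons of strain and age, with SE as bars. Filled points had an edgeR adjusted p under 0.05 and open points did not, and genes with 3 or fewer counts in a group are left out there. gst-5 rose by 3.04 to 5.02 in N2, 3.55 and 1.74 in PX991 and 3.13 and 3.49 in EU1.

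Across the 9 comparisons of SFN with DMSO, none of which share libraries, 7 genes rose in every one and 0 fell in every one: gst-37, gst-5, stdh-2, cdr-4, cyp-13A10, C15B12.8 and ZK697.14. This count was made after the values were seen, and rests for gst-37 on the day 4 value of EU1. In PX991 and EU1 at day 4, gst-5 had edgeR adjusted p = 1.4e-08 and 7.1e-06.

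Differences between the strains in their response to SFN were tested directly. At day 12, the response of PX991 differed from that of N2 for 494 of 12589 genes, 121 higher and 373 lower. The lysozyme ilys-2 (4.03 ± 0.76) and trx-3 (3.59 ± 0.62), which fell in N2, and dod-23 (2.76 ± 0.46) responded higher in PX991 (n = 4 per group, edgeR adjusted p from 2e-04 to 0.0013). The transporter pgp-12 responded less, with a difference of -3.97 ± 0.52, as did ugt-26 (-3.82 ± 0.51), ugt-25 (-3.56 ± 0.49), cyp-13A10 (-2.96 ± 0.52) and cdr-4 (-2.07 ± 0.40) (adjusted p from 4.1e-06 to 0.0017), and all 5 had risen in N2. For gst-4 the difference was -2.21 (0.14), for vit-3 0.68 ± 0.69 (0.64) and for lys-7 0.58 ± 0.91 (0.78). At day 4, 32 genes differed, led by the mitochondrial genes WBGene00010961 (3.86 ± 0.60, 0.0015) and ND3 (3.49 ± 0.59, 0.0022), which had fallen in N2. That count was 255, 310 and 19 without N2 DMSO replicate 1, DMSO replicate 3 and SFN replicate 1, 14, 15 and 7 without PX991 DMSO replicates 2, 3 and 4, and 93, 7, 16 and 18 without PX991 SFN replicates 1 to 4. The day 12 count was 273 and 222 without N2 DMSO replicate 1 and N2 SFN replicate 1, 46 higher and 128 lower without PX991 DMSO replicate 1, and 302 without PX991 SFN replicate 4.

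For EU1 against N2, 1209 genes differed in response at day 4, 421 higher and 788 lower, or 249 higher and 1010 lower with DESeq2's size factors, which moved the median of all genes by -0.11. The response was lower for the peptide transporter gene pept-3 (-4.47 ± 0.63) and ugt-25 (-1.96 ± 0.44), and for ND3 (3.27 ± 0.56), ND6 (2.64 ± 0.63) and the linker histone hil-2 (1.60 ± 0.35) it was higher (edgeR adjusted p from 1.3e-05 to 0.0079). The count was 610 without EU1 DMSO replicate 6 and 2091 without N2 DMSO replicate 3. At day 12, the test gave 182 genes, 42 higher and 140 lower, but 6 of 100 splits of the libraries, the real one included, gave as many (highest other 1120), and so did 4 of 100 that exchanged EU1 libraries within their pairs (1314). Chance is therefore excluded narrowly with the pairs kept and not without them. By this test gst-35 (-3.54 ± 0.78), far-3 (-2.85 ± 0.57) and R09E12.9 (-3.60 ± 0.64) responded lower in EU1 (adjusted p from 0.0019 to 0.012), and cpr-2 (3.53 ± 0.75), ilys-2 (3.13 ± 0.69) and dod-23 (2.43 ± 0.42) higher (0.0019 to 0.015). The difference for gst-4 was -2.18 ± 0.88 (0.2), and passed without EU1 SFN replicate 2 (-3.07, adjusted p = 0.033). The day 12 count was 309, 107 and 434 without EU1 DMSO replicates 2, 4 and 6, and 312 and 289 without EU1 SFN replicates 2 and 6. It was 88 and 70 without N2 DMSO replicates 1 and 2, and 55, 61 and 283 without N2 SFN replicates 1, 2 and 4.

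The last question was whether SFN shifts expression along the course of ageing. Sets of 300 genes that fall and 300 that rise with age in trials 2 and 3 were tested in the SFN comparisons. Genes past the threshold are counted here adjusted over the set alone, with the counts adjusted over all genes in square brackets. In this way 156 of 300 age-falling genes rose and 0 fell with SFN in N2 at day 8 [105 and 0], 220 and 1 at day 12 [200 and 0], and 142 and 3 at day 16 [1.3e2 and 3]. Their medians were 0.77, 1.76 and 0.62 (camera adjusted p = 2.6e-45, 8.8e-55 and 2.4e-23, and 0.0084, 0.0058 and 0.04 with an estimated correlation). At day 12 in the mutants, 80 of 287 rose and 0 fell in PX991 [52 and 0], with a median of 0.69 (1.2e-26, and 0.0097 estimated). In EU1 200 of 290 rose and 8 fell [170 and 4], with a median of 1.32 (1.3e-29, and 0.04 estimated). At day 4, 88 rose and 7 fell in N2 [61 and 4] (3.7e-05, adjusted p = 0.37 with an estimated correlation) and 32 of 287 rose and 2 fell in PX991 [12 and 0] (2.9e-10, adjusted p = 0.078 with an estimated correlation). The set did not pass in EU1 (0.78) or in N2 at day 2 (0.89). Age-rising genes fell more often than they rose at day 12 in PX991 (98 and 0 of 286 [57 and 0], 2.4e-18, and 0.026 with an estimated correlation), at day 12 in N2 (95 and 33 of 299 [78 and 28], 5.1e-06), at day 16 in N2 (122 and 26 [1.1e2 and 24], 2.7e-09) and at day 12 in EU1 (94 and 3 of 297 [80 and 3], 7.8e-12). The last 3 did not hold with an estimated correlation, with adjusted p = 0.33, 0.17 and 0.11. The set also passed downward in N2 at day 8 (0.00015), PX991 at day 4 (0.016) and EU1 at day 4 (5.5e-05), with adjusted p = 0.37, 0.47 and 0.37 with an estimated correlation, and did not pass in N2 at day 2 (0.7) or day 4 (0.28). At day 4 in N2 more age-rising genes rose than fell, 47 against 13 [35 and 10], with a median of 0.24. For PX991 at day 4 the unadjusted p was 0.044 and 0.037 without DMSO replicates 3 and 4, and 0.064, 0.11 and 0.067 without SFN replicates 2, 3 and 4, each above the highest unadjusted p that passed over these sets.

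An age predictor trained on trials 2 and 3 had a mean absolute error of 0.541 days on held-out libraries and 1.06 days on the 20 DMSO libraries of the N2 treatment table. With this predictor, SFN libraries had a lower predicted age at the 5 ages of N2, by -0.86 ± 0.266 days at day 2, -1.14 ± 0.55 at day 4, -0.739 ± 0.163 at day 8, -2.29 ± 0.266 at day 12 and -1.34 ± 0.335 at day 16 (n = 4 per group). The exact two-sided permutation test gave p = 0.0286 each, the smallest that 70 splits can give, and adjusted p = 0.0367. The values at days 2 and 4 depended on the predictor. At day 2 they were -0.0919 days with log2 age (exact p = 0.257), -0.62 and -0.0391 days with training on trial 2 or 3 alone (0.0571 and 0.914) and 0.0341 days, the reverse sign, with the mean of age-rising minus age-falling genes (0.914). At day 4 they were -0.41 days with log2 age (0.6), -0.0375 days with training on trial 2 alone (0.743) and -0.399 days with the mean of the 2 sets (0.114). At days 2 and 4 SFN averaged 3 and 4.25 days and DMSO 3.86 and 5.39, further above its age. DMSO libraries with the fewest genes were highest (4.55 and 6.97 days), and without them differences were -0.628 and -0.61. In PX991 the difference was -2.47 ± 0.458 days at day 12 (exact p = 0.0286, adjusted 0.0367) and -0.314 ± 0.219 days at day 4 (exact p = 0.229). In EU1 it was -1.92 ± 0.375 days at day 12 (n = 6, exact p = 0.00433, adjusted 0.0367, and -1.92 days with exact p = 0.0125 within collections). At day 4 it was -0.445 ± 0.323 days (exact p = 0.249, and -0.43 days with 0.3 within collections). The effects of the mutants did not differ detectably from that of N2 (permutation p = 0.12 and 0.74 for PX991 and 0.29 and 0.4 for EU1 at days 4 and 12). Over all ages of N2 the mean difference was -1.27 days (permutation p = 1e-05, the smallest that the permutations can give). Predicted age rose by 0.786 days per day with SFN and 0.845 in DMSO, a difference of -0.0582 (permutation p = 0.27). This too depended on the predictor, with slope differences of -0.157 (log2 age, permutation p = 0.00305), -0.148 and -0.153 (trial 2 or 3 alone, 0.00534 and 0.0111) and -0.219 (mean of the 2 sets, 0.00044). Leaving out any SFN library of day 2, 4 or 16 raised the exact p to 0.0571. So did DMSO replicate 1 or 2 of day 16, and DMSO replicate 3 or 4 or SFN replicate 2 of day 8. All SFN libraries still lay below all DMSO libraries (-0.657 to -1.52 days).

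**Figure D5:**
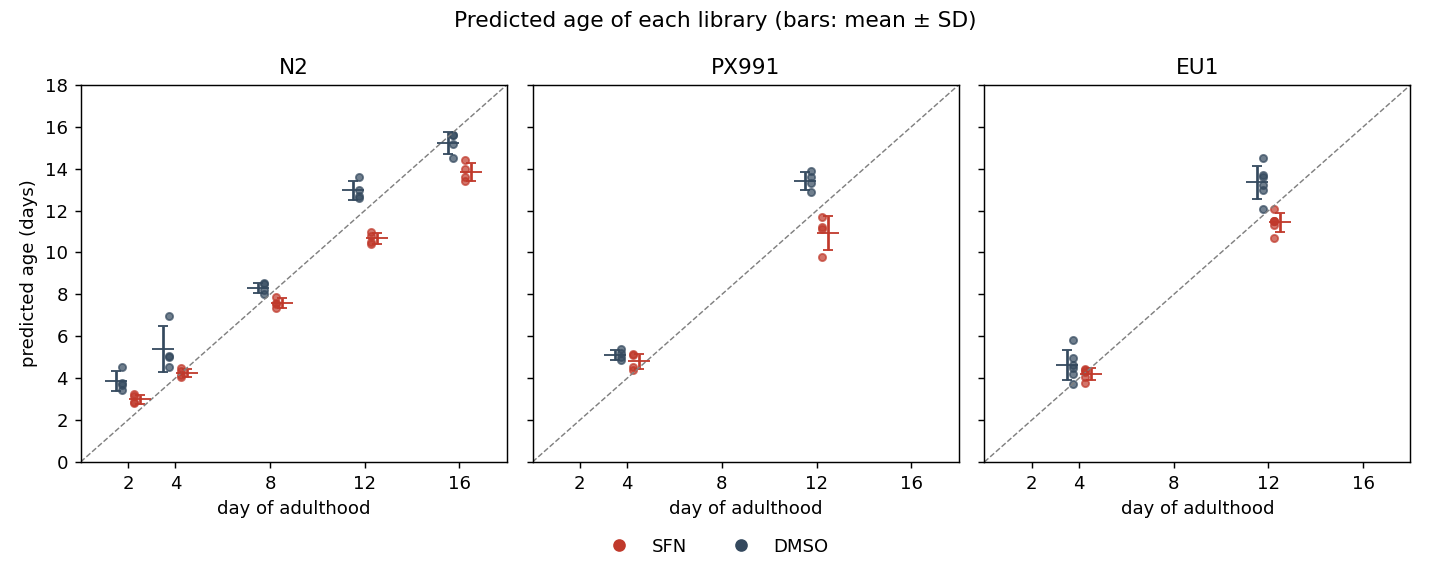
Age predicted from expression in each library against its age in days, for N2, PX991 and EU1, with the mean and SD of each group and a dashed line where the values are equal. In N2 at day 12 the SFN libraries averaged 10.7 days and the DMSO libraries 13 days.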

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

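The tests of the library preparation batch and of EU1 replicate 2 were chosen after the result was seen, as were the comparison of N2 with EU1 and the fits without the DMSO libraries that showed the fewest genes and the age predictor without SFN-responsive genes. In 192 tests, for each measure and group of 4 to 6 libraries, the highest and lowest value were compared with the others. In 19 tests 1 library stood far apart, where chance gives about 1 in 20 tests. By rRNA share these were PX991 DMSO day 4 replicate 4 at 15.4%, EU1 DMSO day 4 replicate 3 at 36.7% and EU1 SFN day 4 replicate 3 at 47.9%. By genes seen at the common depth they were N2 DMSO day 2 replicate 1 with 7116, EU1 DMSO day 4 replicate 6 with 11685 and EU1 SFN day 4 replicate 3 with 9420. By total counts they were N2 DMSO day 12 replicate 4 with 12.5 M, EU1 DMSO day 12 replicate 6 with 8.46 M and EU1 SFN day 12 replicate 6 with 10.3 M.

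Among the 5 genes looked at in every group, daf-16 stood apart at 157 CPM in PX991 DMSO day 12 replicate 3 and skn-1 at 157 CPM in PX991 DMSO day 12 replicate 1. gst-4 stood apart at 30.1 CPM in N2 SFN day 8 replicate 3, 34.4 CPM in PX991 SFN day 12 replicate 1, 28.4 CPM in EU1 SFN day 4 replicate 2 and 15 CPM in EU1 SFN day 12 replicate 2. gcs-1 did so at 91.9 CPM in EU1 SFN day 12 replicate 4. sod-3 did so at 0.867 CPM in N2 SFN day 2 replicate 4, 0.52 CPM in PX991 SFN day 12 replicate 2 and 4.88 CPM in EU1 DMSO day 12 replicate 1.

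The effect of SFN differed, by tests of the difference itself, between the ages of N2 for 1657 genes, between PX991 and N2 for 32 genes at day 4 and 494 at day 12, and between EU1 and N2 for 1209 genes at day 4. For EU1 against N2 at day 12 the test gave 182 genes, a count that 6 of 100 splits reached, or 4 of 100 with the pairs of EU1 kept. gst-4 differed between ages (edgeR adjusted p = 1.2e-07), as did daf-16 (0.015). The response of daf-16 in EU1 at day 4 differed from that in N2 by -0.57 ± 0.18 (0.038). Without 1 library that adjusted p was 0.057, 0.091, 0.067 and 0.055 (N2 SFN replicates 1 to 4), 0.068 and 0.074 (N2 DMSO replicates 2 and 4), 0.067, 0.062 and 0.06 (EU1 SFN replicates 2, 4 and 6) and 0.066 (EU1 DMSO replicate 3).

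The first pattern weighed was the number of genes that passed for SFN in N2 at ages other than day 8. In the wells of the column names, SFN and DMSO libraries alternate within a column at day 8 alone. If they shared a plate there and batch were the whole cause elsewhere, genes that passed at other ages would go either way at day 8. Of those from day 2, 54.6% went the same way (95% interval 50.4 to 58.8), against 73.8% (71.3 to 76.1) from day 4, 89.4% (88.1 to 90.6) from day 12 and 71.7% (69.9 to 73.5) from day 16. However, at least 2 plates were used, and a shared plate at day 8 is not shown. Batch and treatment therefore cannot be told apart by these values, at day 8 or elsewhere. If a batch of the N2 table alone were the whole cause, its genes would go the same way in EU1 no more often than in splits of EU1 that part every pair. Of the genes from days 12 and 16, 87.6% and 81% went the same way in EU1 at day 12, while 2 and 3 of 32 splits, the real one included, reached as much in either direction (highest others 88 and 82.3%). Of those from days 2 and 4, 36.9% and 28% went the same way in EU1 at day 4 (highest others 64.2 and 83.5%), so this excludes batch at none of the 4 ages. When the 2 DMSO libraries of the age with under 10000 genes were left out, 45% (248) of the genes passed again at day 2 and 36.5% (478) at day 4. Their median fold went from 0.67 to 0.62 and from 0.85 to 0.70 (median SE 0.16 to 0.17 and 0.22 to 0.23), but these genes were chosen with the libraries that remained. With any other 2 DMSO libraries left out these shares ran from 38.7 to 73.9% and from 36.5 to 83.8%, so the loss of calls does not show an effect of low yield, which stays open. Batch stays open at days 2, 4, 8, 12 and 16, as the whole cause or as a part of it. A response that changes with age stays open too.

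The second pattern was the lower predicted age with SFN. If the rRNA share of the libraries were its cause, the trend of predicted age on rRNA within groups would account for it, and it accounted for 1.92% of the difference in N2 at day 8, 3.67% at day 12 and 5.2% at day 16, and for 3.31% in PX991 and 0.589% in EU1 at day 12. The widest 95% interval, at N2 day 16, ran from -15.5 to 25.9%, which argues against rRNA share as the whole cause. With genes that respond to SFN at day 2 left out of the predictor, 96.9%, 102% and 103% of the difference was kept in N2 at days 8, 12 and 16, and 99.7% and 101% in PX991 and EU1 at day 12. This decides nothing, since 1 of the 65 genes of the predictor was left out in this way, while 17, 38 and 28 of them passed for SFN in N2 at days 8, 12 and 16, and 23 and 34 in PX991 and EU1 at day 12. Genes that respond to SFN apart from ageing therefore stay open. A batch effect, a change in the share of tissues and slower ageing stay open, and the last was not tested, since expression alone does not measure ageing.

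The third pattern was gst-4 in EU1, which was high in SFN replicate 2 at both ages, 28.4 and 15 CPM. Worms without the skn-1 mutation in these libraries would raise the genes whose response at day 12 was higher in N2 than in EU1. Over 135 such genes, replicate 2 had a median difference from the other SFN libraries of -0.14 at day 4 and 0.1 at day 12, while the other replicates ran from -0.11 to 0.18 and from -0.16 to 0.22, but the comparison that chose these genes used replicate 2 itself, and 6 of 100 splits gave as many genes as it did. In replicate 2 skn-1 was at 117 CPM at day 4, the highest of 5 EU1 SFN libraries (lowest 81.9 CPM), and 98.7 CPM at day 12 (others 77.2 to 121 CPM), against 213 to 247 CPM and 125 to 215 CPM in PX991 with SFN. What skn-1 level such worms would bring is not known, so they stay open at both ages. A difference between collections or in dose stays open, and no biological explanation was tested.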

How the results depend on the processing

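The fits without the DMSO libraries with the fewest genes, without EU1 libraries high in rRNA or gst-4 and without rRNA genes, and the age predictors without SFN-responsive genes, were chosen after the result was seen. For named genes, 7653 of 8139 values with 1 library left out kept their direction and side of the threshold, 478 fell short of it, 8 passed it and 0 reversed. With the DESeq2 test 474 of 488 were the same, with limma-voom 420 of 488, with DESeq2 size factors 614 of 638, with no filter 472 of 488, with the strict filter 437 of 440, with replicate blocks 611 of 638, with no collection term 109 of 146, with only the 2 groups 184 of 223 and with rRNA genes removed 634 of 637, and 0 reversed. Where not stated below, the cause of a change was not tested.

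The DESeq2 test called 1145 and 2209 genes in N2 at days 2 and 4, 2820 that differed between ages, 96 in PX991 at day 4, 206 in EU1 at day 4, and 208, 909, 1904 and 545 for the responses of PX991 (days 4, 12) and EU1 (4, 12) against N2. With no filter, counts were 697 in N2 at day 8, 115 and 712 in PX991 (4, 12), 449 in EU1 at day 4, and 186, 761 and 421 for PX991 (4, 12) and EU1 at day 12 against N2. limma-voom called 1589, 791, 1669, 4903 and 4445 in N2 (days 2 to 16), 1780 for DMSO day 4 against 2, 3183 that differed between ages, 271 in PX991 at day 4, 14 and 1153 in EU1 (4, 12), and 17 and 358 for PX991 and EU1 at day 4 against N2. With only the 2 groups, counts were 28, 41, 1287 and 4171 in N2 (2, 4, 8, 12) and 189 and 163 in PX991 (4, 12). This fit leaves fewer residual degrees of freedom, yet in N2 its counts fell at days 2 and 4 and rose at days 8 and 12. Without the DMSO libraries with the fewest genes they were 1124, 2313, 3809 and 3699 in N2 (2, 4, 12, 16), 2915 that differed between ages, and 813 and 568 for PX991 and EU1 at day 12 against N2. EU1 at day 4 gave 17 with DESeq2 size factors, 12 with no collection term and no replicate block, 14 less its 2 libraries high in rRNA and 12 less the 2 high in gst-4. Replicates 1 to 3 gave 285 and 653 in EU1 (4, 12), and 4 to 6 gave 8 and 589. PX991 at day 4 against N2 gave 8 with no collection term, 56 less the rRNA libraries and 67 with the strict filter. EU1 at day 12 against N2 gave 1.1e2, 290 and 305 in turn, and 289 less the gst-4 libraries.

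With 1 library left out, counts ran from 183 to 665, 755 to 2167, 270 to 454, 1888 to 2245 and 1742 to 2469 in N2 (days 2 to 16), 4047 to 5123 for the mean of ages, 1382 to 2204 that differed between ages, 31 to 41 and 337 to 630 in PX991 (4, 12), 10 to 107 and 1205 to 2221 in EU1 (4, 12), and 7 to 310, 1.7e2 to 659, 610 to 2091 and 55 to 434 for PX991 (4, 12) and EU1 (4, 12) against N2. For ageing they ran from 3142 to 3678, 4975 to 6169, 5585 to 6526 and 6366 to 7187 in the treatment table (days 4 to 16), 1745 to 1966, 4433 to 4666, 6742 to 7063 and 7313 to 7613 in trials 2 and 3, and 7963 to 8196 for the slope on age. Predicted age differences ran from -1.01 to -0.628, -1.43 to -0.61, -0.84 to -0.657, -2.42 to -2.09 and -1.57 to -1.19 days in N2 (2 to 16), -1.33 to -1.17 for their mean, -0.426 to -0.186 and -2.7 to -2.08 in PX991 (4, 12), -0.633 to -0.205 and -2.16 to -1.69 in EU1 (4, 12), and the slope difference from -0.0759 to -0.0478. The age-rising set in PX991 at day 4 had p from 6.3e-06 to 0.11.

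Replicate numbers do not pair the libraries of N2 and PX991 (correlations of -0.13 to 0.29 and -0.14 to 0.16, not all best with their own number). With replicate blocks, PX991 at day 4 against N2 gave 15 genes, and camera gave autophagy in PX991 at day 4 an adjusted p of 0.053 (0.045 without blocks). With the block, exact sign flips over 4 pairs cannot go below p = 0.125 for predicted age (-0.86, -1.14, -0.739, -2.29 and -1.34 days in N2, -2.47 in PX991 at day 12). In EU1 the blocks changed no call beyond those in the report.

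With an estimated correlation, camera called 0, 0, 3, 4 and 3 lists in N2 (2 to 16), 1 for the mean of ages, 2 and 0 in PX991 and 0 and 0 in EU1 (4, 12). The age-falling set had adjusted p = 0.37 in N2 and 0.078 in PX991 at day 4, and the age-rising set 0.37, 0.33, 0.17 and 0.37 in N2 (8, 12, 16, mean), 0.47 in PX991 at day 4 and 0.37 and 0.11 in EU1 (4, 12). Falling sets in N2 at day 4 had 0.16 with 1000 genes and 0.11 from trial 2, rising sets from trial 2 had 0.005 at day 4 and 0.4 for the mean, and the rising set from trial 3 had 0.29 in EU1 at day 4.

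Predictors of log2 age gave -0.0919, -0.41 and -0.59 days in N2 (2, 4, 8) and a slope difference of -0.157. Training on trial 2 gave -0.62 and -0.0375 (2, 4) and slope -0.148, and on trial 3 -0.0391 (2) and slope -0.153. Binarized values gave -2.03 and -1.88 (2, 16), and a filter of 10 CPM -1.11 (4). The mean of rising minus falling genes gave 0.0341 at day 2, a reversed sign, -0.399 (4), -0.857 in PX991 (4) and slope -0.219. Without SFN-responsive genes day 4 gave -1.13, and without rRNA genes -1.17.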

Other observations

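All splits of libraries here were planned, except those within pairs of EU1 for its response against N2, which, like the counts of genes shared between comparisons, were chosen after the result was seen. In N2, gst-24 rose by 0.91 ± 0.17, 1.32 ± 0.17, 1.77 ± 0.16, 3.23 ± 0.17 and 2.34 ± 0.17 at days 2, 4, 8, 12 and 16, and the glucuronosyltransferase ugt-46 by 1.33 ± 0.27, 2.39 ± 0.28, 2.68 ± 0.29, 3.13 ± 0.28 and 2.24 ± 0.27 (n = 4). In the mutants, ugt-46 rose by 2.13 ± 0.21 in PX991 at day 4 (edgeR adjusted p = 9.6e-07) and 2.47 ± 0.33 in EU1 at day 12 (2.8e-05), and gst-24 by 2.15 ± 0.19 in EU1 at day 12 (6.5e-07). The P450 gene cyp-25A2 rose at day 12 by 2.68 ± 0.25 in N2, 1.74 ± 0.31 in PX991 and 2.44 ± 0.23 in EU1. Of DAF-16-regulated genes, dod-24 rose by 2.97 ± 0.39 in N2 at day 12, while dod-23 fell there by 1.80 ± 0.19 on the log2 scale.

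Of the genes that passed in PX991 at day 12, 381 of 471 went the same way in N2 at day 12 and 431 of 466 in EU1 at day 12. Of those that passed in EU1 at day 12, 1792 of 2144 went the same way in N2 at day 12, 914 of them past the threshold there, and 4 passed in the opposite direction. Of those that passed in N2 at day 12, 677 of 2242 went the same way in EU1 at day 4.

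Other splits of the libraries into groups of the same sizes were fitted in the same way, all 35 for 4 against 4 and 100 drawn otherwise, the real split included in each count. For genes past the threshold, chance can be excluded in N2 at days 2 (551, highest other 20), 4 (1311, 283), 8 (449, 0), 12 (2396, 2) and 16 (2463, 176), for the mean of ages (4325, 124) and for the difference between ages (1657, 1300), with 1 split as large, the real one, in each. The same holds for PX991 at days 4 (51, 0) and 12 (472, 17), EU1 at day 12 (2155, 1010), and the response of EU1 against N2 at day 4 (1209, 81). In EU1 at day 4, 3 of 100 splits reached 28 genes, with a highest other of 69, while among the 32 splits that part every pair the highest other was 5 at day 4 and 2 at day 12. For PX991 against N2, 3 of 100 splits reached 32 genes at day 4 (highest other 223) and 3 reached 494 at day 12 (1200). Chance is thus excluded only narrowly in these drawn splits, and these other counts point to a structure of the samples. For EU1 against N2 at day 12, 6 of 100 splits reached 182 genes, with a highest other of 1120, so chance cannot be excluded there, and that count too points to a structure of the samples. With EU1 libraries exchanged within their pairs, 4 of 100 splits reached 182 genes (highest other 1314), and 1 of 100 reached 1209 at day 4 (highest other 226), which does not exclude chance, for the same reason. Splits that exchange SFN and DMSO in N2 can hold the effect that the strains share, which may raise such counts, but this was not tested. Ageing in DMSO against day 2 excluded chance at days 4, 8, 12 and 16 in the treatment table (3368, 5545, 6033 and 6714 genes, highest others 1970, 1300, 1880 and 2400), in trials 2 and 3 (2009, 4651, 6929 and 7429, highest others 22, 572, 4450 and 5730) and for the slope on age (7929, 96).

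For the size, without sign, of the difference between the mean log2 fold changes of age-falling and age-rising genes, chance can be excluded in N2 at days 8 (0.994, highest other 0.677), 12 (1.97, 1.11) and 16 (1.16, 0.803) and for the mean of ages (0.836, 0.485), in PX991 at days 4 (0.397, 0.322) and 12 (1.56, 1), and in EU1 at day 12 (1.67, 1.55). It cannot be excluded in N2 at day 2 (0.0584, age-rising genes higher, with 21 of 35 splits as large and a highest other of 0.253) or day 4 (0.117, 5 of 35, 0.181), or in EU1 at day 4 (0.198, 48 of 100, 0.681). For the number of gene lists past camera at the preset correlation, chance can be excluded in PX991 at day 12 (17, highest other 14) and for the mean of ages of N2 (18, 2 of 100 as large, 20). It cannot be excluded in N2 at day 2 (8, 13 of 35, 11), day 4 (14, 2 of 35, 15), day 8 (17, 4 of 35, 18), day 12 (19, 8 of 35, 20) or day 16 (19, 4 of 35, 19), in PX991 at day 4 (12, 5 of 35, 15) or in EU1 at day 4 (11, 41 of 100, 18) or day 12 (15, 20 of 100, 19), so the number of lists at the preset correlation is no evidence by itself.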
